A study of Mus musculus with 2 samples.

How the data were processed

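The data were 2 droplet libraries (10x Genomics, 3′ gene expression) of sorted small intestine lamina propria cells, 1 pool of 3 mice per genotype, sequenced towards 50000 read pairs per cell. The UMI counts were made before they were deposited, per the labels with Cell Ranger 7.2.0 against the mouse genome (mm10, GRCm38). Seurat 5.0.1, named in the same notes for later steps, and its cell filtering and cell type calls were not used here. The deposited count matrices were unfiltered, with 32285 genes and 2307624 barcodes in the F/F library and 2270301 in the CD4-Cre library. Values were whole UMI counts and were used as deposited. All 339 named genes and list members were matched by identifier to GENCODE M21, which gave positions on GRCm38.

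Cells were barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. There were 13843 F/F and 13644 CD4-Cre barcodes with enough UMIs, 13439 and 13220 also with enough genes, and 12594 and 12526 after the mitochondrial limit. The kept cells had a median of 2113 and 2039.5 genes and held 198152238 and 177456457 UMIs. Scrublet called 0 doublets at thresholds of 0.647 and 0.657, which is not credible for so many cells, so doublets remain in the data and keeping or removing its calls is the same thing. Both libraries were clustered together (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, seed 1) with immunoglobulin, T cell receptor, mitochondrial and ribosomal genes, Gramd1a and the genes of 12 readout lists left out of the variable genes. The 24 clusters were named from fixed markers of 22 cell classes: at least 3 markers detected in 20% of cells and leading among the top 10 genes. Further limits on the share of cells with Trac, Cd4, Cd8a, Cd8b1, Cd3e and Trdc separated T cell classes and were set after the data were seen. This named 10 classes, of which 8 clusters were plasma-like and 2 CD4 T-like, and left 6 clusters unnamed, among them clusters with leading genes of several T, NK and innate lymphoid classes. Class names end in -like because they rest on transcripts alone.

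For each class, UMIs were summed over cells and scaled by the class total (CPM, over all genes). Log2 ratios of the CD4-Cre over the F/F library carry exact 95% intervals from the binomial split of UMIs, and shares of cells carry exact Clopper-Pearson intervals. Because a pool is 1 sample, these intervals leave out variation between mice, so no p-value is given and no number of changed genes. The intervals of CPM ratios also treat UMIs as independent, although 1 cell can hold many UMIs of a gene. A count of 0 allows 3 counts. Cells were also thinned to 1500 UMIs to compare shares of cells with a UMI at equal depth. Classes needed 100 cells in both libraries for gene comparisons. Named genes had at least 100 UMIs over both libraries, at least 20 CPM in 1 of them, and an interval bound at least 0.2 from 0 on the log2 scale, ranked by that bound: up to 12 per direction in CD4 T-like cells, 6 in CD8 T-like cells and 4 in other classes. Gramd1a, Gramd1b, Gramd1c, Il17a, Il17f, Il22, Ifng, Il10 and Foxp3 were always named. The same rule was repeated without genes whose free RNA differed over 4-fold between the libraries, a repeat chosen after the data were seen; other genes in the text are cytokines of a fixed set or, for each list, up to 4 members with the largest bound. Tnfrsf9 fell outside the rule and was chosen after its values were seen. Some results that the rule names were left out because they are withheld for evaluation.

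Gene lists, 25 in number, were fixed before the data were examined, as were the filters, the markers and the rule for named genes. They covered sterol transport and the Aster family, cholesterol synthesis and SREBP2 targets, LXR targets and fatty acid synthesis, type 17, type 1 and type 2 programs, regulatory, follicular helper and naive T cells, T cell receptor activation, immediate early and dissociation genes, glycolysis and mTORC1, oxidative phosphorylation, the interferon response, cytotoxicity, proliferation, gut homing, MHC class II presentation, ILC3 effectors, ribosomal proteins, and RNA of plasma, enterocyte, erythroid, stromal and mast cells. Members needed 20 UMIs over both libraries, 0.5 counts were added, and intervals came from 1000 Poisson redraws. Each median was placed among 10000 random lists drawn from 100 genes of like expression per member; this percentile describes these libraries and is not a test. In a test on simulated CD4 T-like pools with 5295 genes, 94.9% of intervals held the true ratio. Of unchanged genes 0.157% passed the bound, and 72.1% of genes changed 1.5-fold and 100% of those changed 2-fold did. The pools were drawn as Poisson counts, the model behind the intervals, so this checks the calculation only. UMIs that gather in few cells were not simulated, so the intervals of such genes are too narrow. Of 200 unchanged lists, 12.5% fell outside the middle 90% of random lists, so a percentile alone overstates how unusual a list is.

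Free RNA was read from barcodes with 10 to 100 UMIs, and from 62471 F/F and 62632 CD4-Cre barcodes with 150 to 350 UMIs, a plateau chosen after the data were seen. Alternatives fixed in advance changed the UMI, mitochondrial and doublet filters, the resolution, the clustering genes, the scaling, free RNA subtraction, the weight of cells, the definition of CD4 T-like cells, thinning, the denominator of shares and the list minimum. Alternatives added after seeing the data were subtraction with the plateau profile, clustering without free RNA genes or without Cd4, leaving out CD4 T-like cells over 8000 UMIs or 10% immunoglobulin, adding the cycling T cluster with or without its highest Il17a cell, a reduced denominator, and leaving out the 5 highest cells per gene and library. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, umap-learn 0.5.12, scikit-learn 1.9.0 and matplotlib 3.10.9.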

Results

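Transcriptomes of single immune cells were collected from the lamina propria of the mouse small intestine, the connective tissue layer beneath the gut epithelium. The mice carried floxed alleles of Aster-A, an endoplasmic reticulum protein encoded by Gramd1a that moves cholesterol between membranes without vesicles. The control pool carried the floxed alleles alone (F/F), and the other pool also carried CD4-Cre, a transgene that deletes floxed segments in αβ T cells during thymic development. Female littermates aged 10 to 12 weeks were fasted for 16 h and then received olive oil by gavage for 2 h. Live cells with CD45 and without EPCAM, Ter119 or CD31 were sorted, 100000 from each mouse, and the cells of 3 mice per genotype were pooled into 1 library. The comparison therefore asks which immune cells and transcripts differed between the pools after a lipid meal. The F/F library held 222838658 unique molecular identifiers (UMIs) and the CD4-Cre library 200580083. Filtering kept 12594 F/F cells with a median of 15319.5 UMIs and 12526 CD4-Cre cells with a median of 14031 UMIs. With 1 pool per genotype there were no biological replicates and nothing was tested. Intervals are 95% intervals that cover counting error only, and ratios are those of the CD4-Cre over the F/F library.

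Gramd1a (ENSMUSG00000001248; chromosome 7, 31130127 to 31155896, minus strand, GRCm38) was the targeted gene. In CD4 T-like cells it stood at 51.4 CPM (UMIs scaled by the total of the class in each library) in F/F and 41.7 CPM in CD4-Cre, a ratio of 0.812 (0.659 to 1.001). The ratio was 0.675 (0.471 to 0.966) in the CD4 T-like cluster that holds most Foxp3 cells and 0.852 (0.655 to 1.11) in the other CD4 T-like cluster. It was 0.775 (0.536 to 1.14) in CD8 T-like cells, 0.962 (0.89 to 1.04) in plasma-like cells, 0.908 (0.703 to 1.17) in macrophage-like cells and 1.19 (0.881 to 1.63) in cDC1-like cells. ILC3-like cells stood at 0.638 (0.396 to 1.02), from 41 and 36 UMIs, with 99 F/F cells, under the limit for gene comparisons. The unnamed clusters 0, 13 and 17 stood at 0.789 (0.653 to 0.953), 0.995 (0.773 to 1.28) and 0.923 (0.728 to 1.18). B-like and ILC2-like cells lay above 1, at 1.14 and 1.65. Ratios under 1 were thus not limited to the CD4 T-like and CD8 T-like classes, but most of these intervals reached 1. Outside the CD4 T-like clusters, only the interval of cluster 0 lay under 1. Cd3e was seen in 65.9% and Trac in 44.0% of the cells of cluster 0, so it may hold cells that CD4-Cre targets. Its relatives Gramd1b and Gramd1c, which encode Aster-B and Aster-C, had ratios of 1.01 (0.879 to 1.17) and 1.22 (0.682 to 2.24) in CD4 T-like cells. The floxed exons are not given in the sources used here, and the annotation lists 14 transcripts of Gramd1a. UMIs of a 3′ library come from the transcript end, and a tag outside the deleted part checks nothing, so these values neither show nor exclude the deletion.

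**Figure D1:**
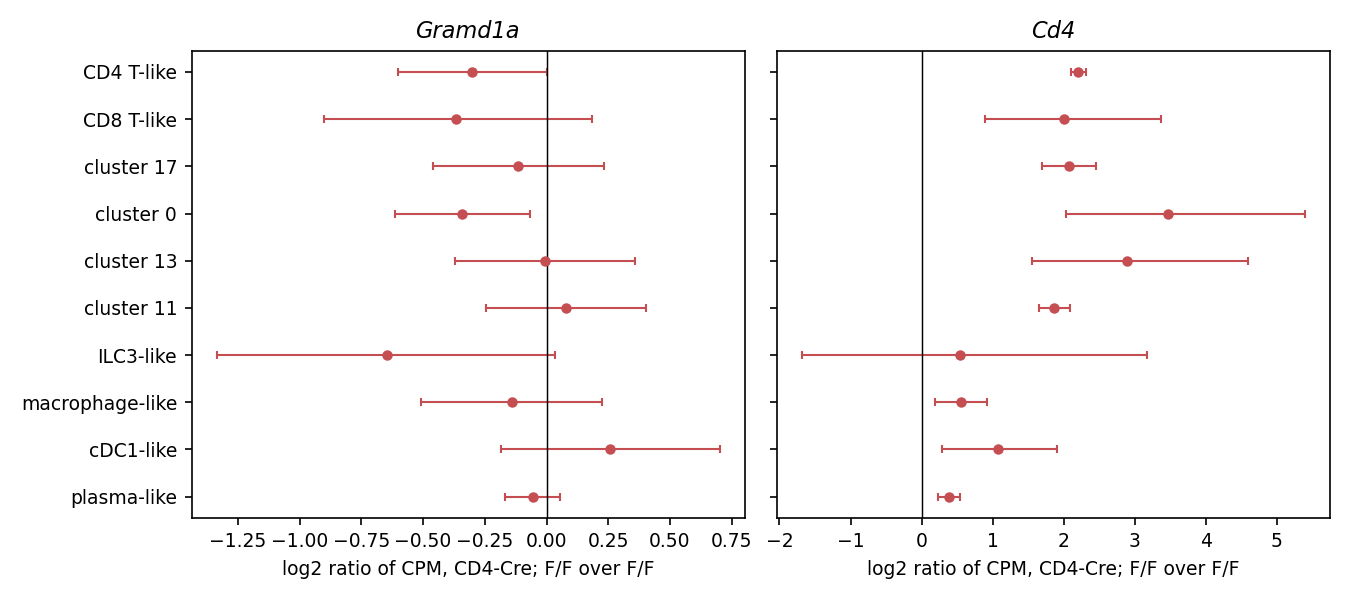
Log2 ratio of CPM between the CD4-Cre and the F/F library for Gramd1a (left) and Cd4 (right) in named cell classes and numbered clusters; points are ratios of summed UMIs and bars are exact 95% counting intervals, with 1 library per genotype. Gramd1a lay at 0.812 times the F/F level in CD4 T-like cells, and Cd4 at 4.62 times.

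CD4 T-like cells made up 6.43% (6.01 to 6.87) of kept F/F cells and 9.59% (9.08 to 10.1) of kept CD4-Cre cells, 810 and 1201 cells. CD8 T-like cells made up 1.04% (0.87 to 1.23) and 2.90% (2.61 to 3.21), a ratio of 2.79 (2.30 to 3.40). Macrophage-like cells were fewer in the CD4-Cre library, 5.96% (5.55 to 6.38) against 4.37% (4.02 to 4.74), and plasma-like cells, the antibody-secreting majority, made up 65.6% (64.7 to 66.4) and 58.5% (57.6 to 59.3). Among the smaller classes, cDC1-like cells, the dendritic cells that cross-present antigen, stood at 2.68% and 3.86%, B-like cells at 0.611% and 1.32%, ILC3-like cells at 0.786% and 1.13%, and ILC2-like cells at 0.341% and 0.487%. Neutrophil-like cells numbered 18 and 40, and stromal-like cells 3 and 13. Cluster 17, led by Nkg7, Il7r and Zbtb16, stayed unnamed and made up 3.03% (2.74 to 3.35) and 6.30% (5.88 to 6.74). Unnamed clusters led by cytotoxic and γδ T cell genes stood at 2.77% and 3.85% (cluster 0, with Xcl1, Klrd1 and Cd160) and at 1.84% and 2.38% (cluster 13, with Trdc and Gzma). Cluster 9, led by the pancreatic enzyme genes Ctrb1, Prss2 and Pnlip, held 694 F/F cells and 1 CD4-Cre cell, and the plasma-like cluster 6 held 861 and 3. Cluster 9 also had plasma cell features, with a median of 50.9% of UMIs on immunoglobulin genes and the plasma marker Xbp1 in 90.5% of cells. The plasma-like share of F/F cells may therefore be understated. With free RNA genes left out of the clustering, a setting chosen after the data were seen, plasma-like cells made up 69.8% and 58.2%. Cluster 11, with T and plasma markers in the same cells, held 366 and 548 cells.

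These shares depend on each other and on the denominator. Among the 3200 F/F and 4489 CD4-Cre cells outside the B-like, plasma-like, pancreatic and mixed clusters, CD4 T-like cells made up 25.3% and 26.8%, cDC1-like cells 10.6% and 10.8%, CD8 T-like cells 4.09% and 8.09%, and macrophage-like cells 23.4% and 12.2%. Cd4 is itself a marker of its class and differed between the libraries; clustering without Cd4 gave 791 and 1165 CD4 T-like cells.

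**Figure D2:**
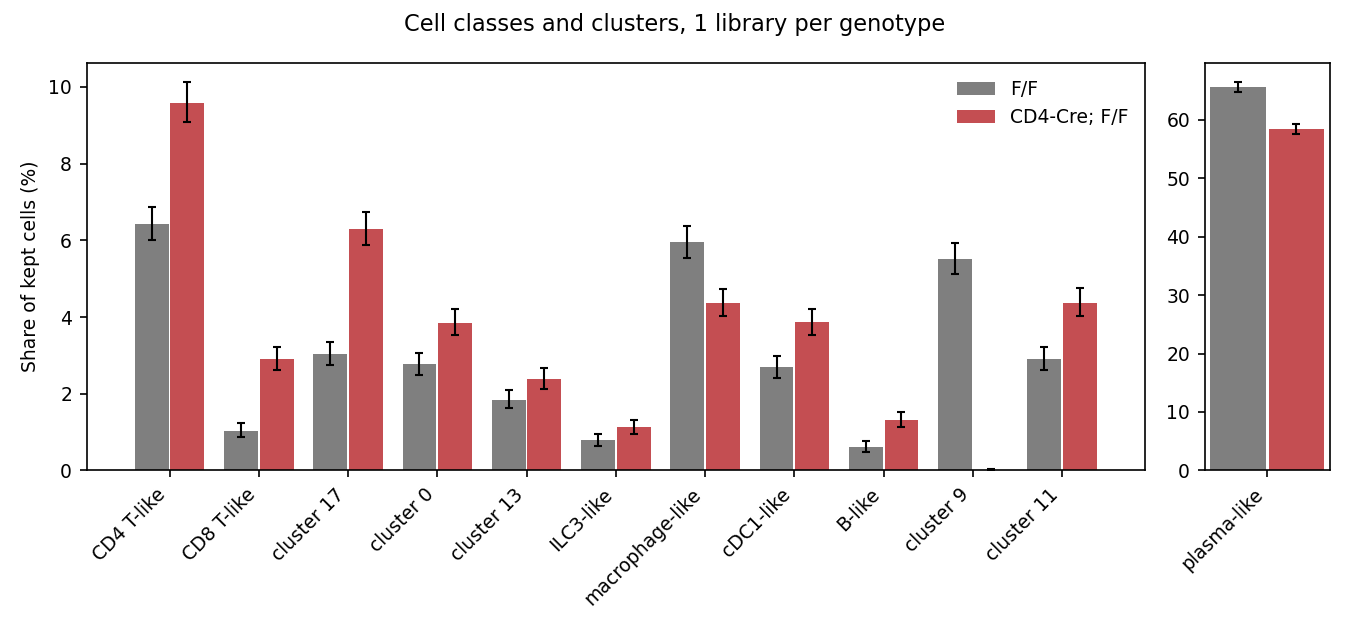
Share of kept cells (%) in each named class or numbered cluster for the F/F library (grey) and the CD4-Cre library (red); plasma-like cells have their own axis, and bars are exact 95% binomial intervals for 1 library per genotype. CD4 T-like cells stood at 6.43% and 9.59%, and macrophage-like cells at 5.96% and 4.37%.

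In CD4 T-like cells, the transcript of the coreceptor gene Cd4 (ENSMUSG00000023274; chromosome 6, 124864692 to 124888221) was higher in the CD4-Cre library, 254 CPM against 1171 CPM, a ratio of 4.62 (4.30 to 4.97). A Cd4 UMI was seen in 57.4% of F/F and 92.8% of CD4-Cre cells of the class. Frmd5 (chromosome 2, 121545529 to 121807087), a leading gene of 1 of the CD4 T-like clusters, was at 294 and 478 CPM, a ratio of 1.63 (1.51 to 1.76). Also higher were Cdk5rap1, with a ratio of 3.50 (2.38 to 5.29), Lsg1 at 2.07 (1.60 to 2.70), Isca1 at 1.93 (1.42 to 2.65), Aff3 at 1.92 (1.46 to 2.56), Ssbp2 at 1.58 (1.33 to 1.88) and Kpna1 at 1.53 (1.37 to 1.71). The replication-linked genes Uhrf1 and Dtl stood at 2.07 (1.41 to 3.10) and 1.93 (1.33 to 2.86), and 3.09% of F/F and 3.33% of CD4-Cre cells held a Uhrf1 UMI. Without cells over 8000 UMIs or 10% immunoglobulin, the log2 ratio of Uhrf1 turned to -0.25. Mbnl1, a splicing regulator on chromosome 3 (60472830 to 60629750), was at 1438 and 2479 CPM, a ratio of 1.72 (1.67 to 1.78). It was also higher in plasma-like cells, where the ratio was 1.63 (1.61 to 1.65), so its difference was not particular to T cells.

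Lower in CD4 T-like cells of the CD4-Cre library were Il17a (ENSMUSG00000025929; chromosome 1, 20730905 to 20734496), the cytokine gene of Th17 cells, and Xcl1 (chromosome 1, 164931644 to 164935527), a chemokine that attracts cDC1 cells. Il17a was at 185 and 83.0 CPM, a ratio of 0.448 (0.394 to 0.509). Xcl1 was at 181 and 54.0 CPM, a ratio of 0.298 (0.256 to 0.345), but 465 of its 614 F/F UMIs came from 5 cells. The share of cells with an Xcl1 UMI was 6.05% and 7.33%, and without the 5 highest cells of each library the ratio was 0.637 (0.50 to 0.811). The chemokine gene Ccl4 stood at 0.434 (0.313 to 0.60), and at 0.766 (0.489 to 1.2) without such cells. Zeb2, also a leading gene of macrophage-like cells, stood at 0.486 (0.384 to 0.614) and Tex14 at 0.594 (0.557 to 0.633). The histone genes Hist1h4n and Hist1h2ac stood at 0.458 and 0.478, and Rdm1 at 0.545 (0.478 to 0.621); Rdm1 was also lower in plasma-like cells, with a ratio of 0.569, and Hist1h4n in macrophage-like cells, with a ratio of 0.382. Pou2af1, Mef2c, Tcf4 and Cacna1e, genes active in B lineage cells, stood at 0.445, 0.539, 0.518 and 0.504. Their level in barcodes without cells was above that in the class; Mef2c was at 258 and 219 CPM there, against 77.4 and 41.7 CPM in CD4 T-like cells.

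The remaining genes picked out by size are known from stomach or pancreas and are called gastric and pancreatic here, but the organ their RNA came from was not tested. The gastric genes Tff2, Gkn3 and Agr2 had ratios of 13.8 (10.8 to 17.8), 14.4 (8.47 to 26.8) and 17.2 (6.51 to 64.5) in CD4 T-like cells, and Tff2 was at 399 and 4841 CPM in barcodes with 150 to 350 UMIs, a range of free RNA barcodes chosen after the data were seen, and at 80.2 and 469 CPM in those with 10 to 100 UMIs. Transcripts of 10 genes expressed by pancreatic acinar cells (Try4, Reg1, Ctrb1, Prss2, Cela2a, Try5, Cela3b, Pnlip, Clps and Cela1) were lower in the CD4-Cre library, with ratios from 0.011 for Reg1 to 0.255 for Cela1. Ctrb1 was at 1894 and 4.2 CPM in the barcodes with 150 to 350 UMIs, and at 227 and 39.1 CPM in those with 10 to 100 UMIs. Genes of this kind differed in the other classes too, including macrophage-like and cDC1-like cells.

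**Figure D3:**
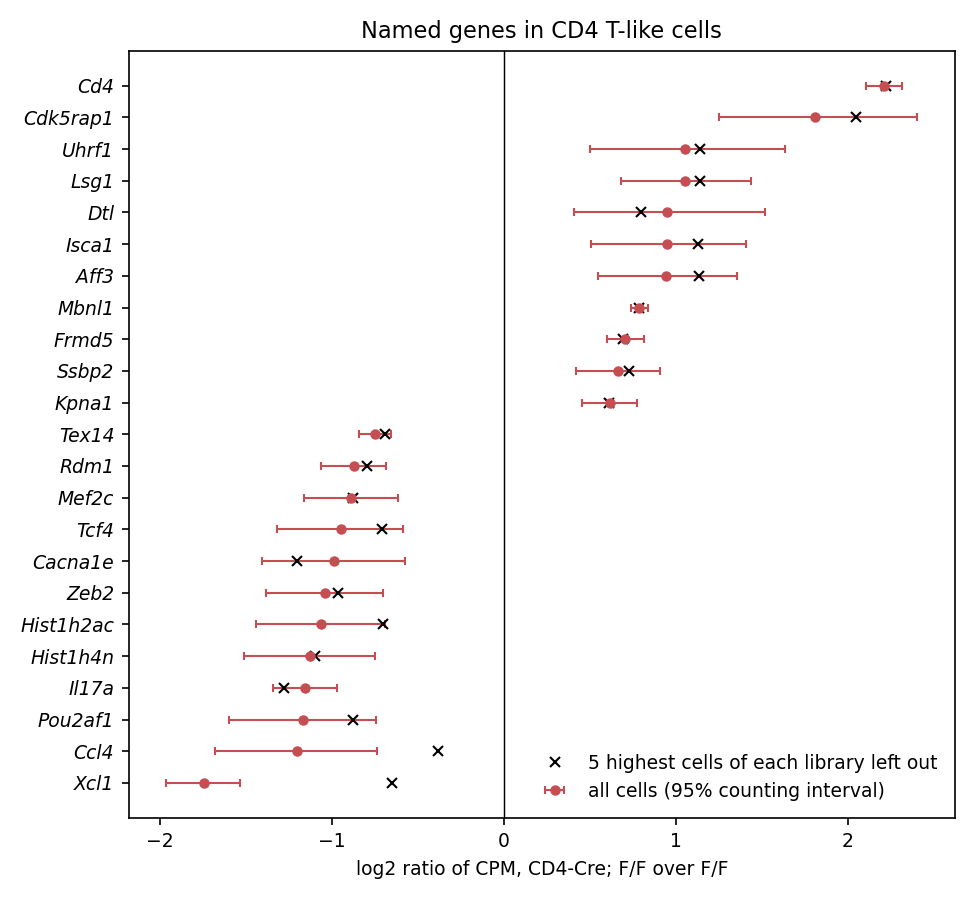
Log2 ratio of CPM between the CD4-Cre and the F/F library for genes named by size in CD4 T-like cells and given in the text, free RNA genes left out; red points with bars are all cells with exact 95% counting intervals, and crosses leave out the 5 cells of each library with the most UMIs of that gene. Cd4 lay highest with a ratio of 4.62, Il17a stood at 0.448, and Xcl1 moved from 0.298 to 0.637.

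Cells with an Il17a UMI made up 9.88% (7.91 to 12.1) of F/F and 6.33% (5.02 to 7.86) of CD4-Cre CD4 T-like cells, 80 of 810 and 76 of 1201. With cells thinned to 1500 UMIs, which left out 35 and 27 shallower cells, the shares were 7.74% (5.96 to 9.85) and 4.43% (3.33 to 5.77). Il17f, its neighbour on chromosome 1 (20777146 to 20790617), was at 16.5 and 4.24 CPM, a ratio of 0.256 (0.146 to 0.434). It was seen in 1.98% and 0.833% of cells, 16 and 10 cells. Without the 5 highest cells of each library the ratio was 0.155 (0.0462 to 0.418), but these are a larger part of 10 than of 16 cells. In the Foxp3-rich cluster 12 the share with Il17a was 13.7% (10.6 to 17.4) and 8.15% (6.07 to 10.7), and in cluster 16 it was 5.68% and 4.58%. Cells with Ifng made up 9.38% (7.46 to 11.6) and 7.58% (6.14 to 9.22), with Il10 33.1% (29.9 to 36.4) and 30.5% (27.9 to 33.2), with Tnf 13.3% and 11.4%, and with Il22 2.96% and 3.25%. Their CPM ratios were 0.948 (0.742 to 1.21) for Ifng, 0.982 (0.907 to 1.06) for Il10 and 0.739 (0.518 to 1.06) for Il22. Il2 was seen in 1.36% (0.68 to 2.42) and 0.416% (0.135 to 0.969) of cells. The regulatory T cell gene Foxp3 was seen in 25.1% and 22.7%, with a CPM ratio of 0.917 (0.797 to 1.06). Il4 and Il21 were seen in 0.617% and 0.666%, and in 1.73% and 1.75%. Il5 was seen in 1 F/F cell, and Il13 and Csf2 in 0 cells of either library, and 3 counts would be shares of cells with a UMI of 0.37% and 0.25%.

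In B-like cells, which should lack Il17a, 1.3% of F/F and 0.606% of CD4-Cre cells held a UMI, at median depths of 8386 and 14403 UMIs against 3514 and 3220 in CD4 T-like cells. The Il17a CPM of CD4 T-like cells depends on 1 CD4-Cre cell with 279 Il17a UMIs, which clustered with the cycling T cells of cluster 18; where another clustering placed it among the CD4 T-like cells, the log2 ratio moved from -1.16 to values between -0.43 and -0.15, and without that cell it was between -1.15 and -0.90.

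**Figure D4:**
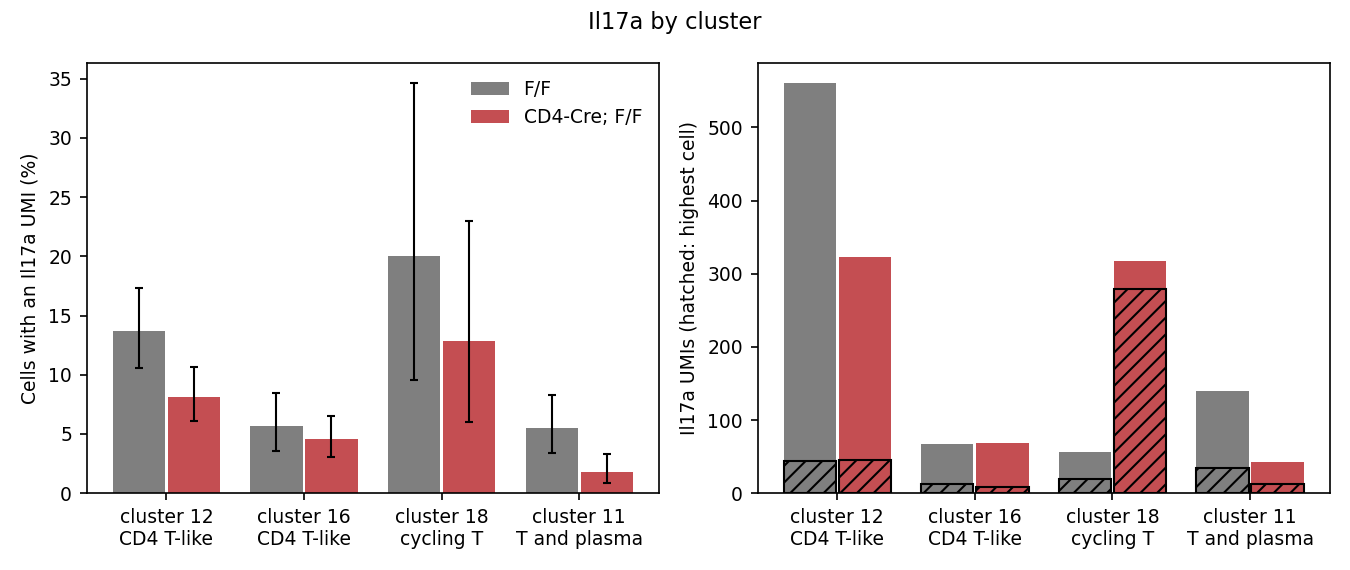
Share of cells with an Il17a UMI (%, left, with exact 95% binomial intervals) and total Il17a UMIs (right, the hatched part being the highest cell) in the clusters that hold most Il17a, for the F/F (grey) and CD4-Cre (red) library. In cluster 12 the share was 13.7% and 8.15%; in cluster 18, 279 of 317 CD4-Cre UMIs came from 1 cell.

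Of the gene lists fixed in advance, T cell receptor activation was lower in CD4 T-like cells of the CD4-Cre library, with 12 of 17 members lower and a median log2 ratio of -0.25 (-0.32 to -0.11), at percentile 0 of 10000 random lists matched on expression. Egr1 had a ratio of 0.665 (0.551 to 0.803), Nr4a1 0.772 (0.64 to 0.93) and Il2 0.239 (0.068 to 0.692), while the surface markers Cd69 and Tnfrsf9 stood at 1.13 (1.08 to 1.19) and 1.16 (1.07 to 1.27). The immediate early and dissociation list, which also reads the handling of cells, had a median of -0.12, with Dnajb1 at 0.644. The same activation list had medians of -0.44 in CD8 T-like, -0.26 in cDC1-like and -0.30 in plasma-like cells, so its shift was not limited to CD4 T-like cells. It was not general either, with medians of 0.06 (-0.09 to 0.19) in macrophage-like cells, -0.02 in cluster 0 and 0.15 (-0.00 to 0.40) in cluster 13. Within the class the median was -0.49 (-0.62 to -0.28) in cluster 16, over 15 measured members, and 0.01 (-0.18 to 0.15) in cluster 12, over 14, and this difference was not tested. At resolution 0.5, where the class shrank to 424 and 590 cells, the median was 0.003. The immediate early list also stood at 0.003 there.

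The type 17 list had a median of -0.15 (-0.35 to 0.00), with 7 of 12 members lower, at percentile 0.33; Il23r, the receptor subunit for IL-23, had a ratio of 0.804 (0.671 to 0.964). With at most 5% mitochondrial UMIs its median was 0.053. All 6 measured members of the ILC3 effector list, 5 of them shared with the type 17 list, were lower, with a median of -0.44 (-0.75 to -0.24). The type 1 list had a median of -0.08, and the type 2 list, with 5 measured members, of 0.01.

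Genes of cholesterol synthesis and SREBP2 targets had a median of -0.08 (-0.24 to 0.04), with 13 of 22 lower, at percentile 2.06. Srebf2, the regulator of the pathway, had a ratio of 0.803 (0.673 to 0.96), and Sc5d, which encodes a late enzyme of synthesis, 0.621 (0.445 to 0.864). The median was -0.38 in cluster 12 and 0.24 in cluster 16, and -0.46 (-0.77 to -0.12) in CD8 T-like cells. In plasma-like cells, which CD4-Cre does not target, it was -0.18, with 21 of 23 lower. LXR targets and fatty acid synthesis genes had a median of 0.05 (-0.11 to 0.27), with the cholesterol exporter gene Abcg1 at 1.61 (1.17 to 2.24) and Fads1 at 0.43 (0.192 to 0.924). Sterol transport and Aster family genes were split, 6 higher and 6 lower, with a median of -0.00; Npc1, which exports cholesterol from lysosomes, had a ratio of 0.928 (0.58 to 1.5).

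Medians of other lists in CD4 T-like cells were 0.06 for regulatory T, 0.09 for follicular helper T, 0.14 for naive and central memory T, 0.05 for gut homing and residence, 0.03 for glycolysis and mTORC1, -0.05 for oxidative phosphorylation, -0.03 for the interferon response and -0.03 for cytotoxicity. The median over genes of the class with at least 100 UMIs was itself 0.08, so a small positive value does not mark a list as higher than other genes. Tcf7 had a ratio of 1.43 (1.18 to 1.74), Itgae 1.23 (1.11 to 1.37), Cd200 0.428, Cxcr6 0.781, Cox6c 0.75 and Ifi27l2a 0.64. Proliferation genes had a median of 0.17 (-0.02 to 0.26), with Mcm3 at 1.38, and MHC class II presentation 0.24 (-0.08 to 0.40), with H2-Aa at 1.49. Ribosomal protein genes had a median of -0.17, and also lay lower in plasma-like cells, at -0.28. Immunoglobulin constant genes, a measure of plasma cell RNA, had a median of -0.22 and a mean of 0.11; the median and mean also differed in sign for the regulatory T and glycolysis lists. Enterocyte, erythroid, stromal and mast cell RNA had no member with enough UMIs in CD4 T-like cells.

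In CD8 T-like cells all 10 cytotoxicity genes were higher in the CD4-Cre library, with a median log2 ratio of 0.45 (0.28 to 0.60), at percentile 99.98. Klrk1, which encodes the activating receptor NKG2D, was at 34 and 125 CPM, a ratio of 3.69 (2.32 to 6.17), Klrd1 had a ratio of 1.71 and Fasl 1.66 (1.22 to 2.32). Gpr183, a receptor for oxysterols, had a ratio of 2.80 (1.91 to 4.25), with 12.2% and 35.5% of cells holding a UMI, Plac8 2.21 (1.75 to 2.81), Mib1 3.34 and Aff1 2.42. Lower were S100a4, with a ratio of 0.262 (0.204 to 0.336), Xcl1 with 0.304 (0.237 to 0.39), Ifi27l2a with 0.347 (0.294 to 0.41) and Lgals1 with 0.466. The share of cells with an Xcl1 UMI was 30.5% and 15.7%.

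Few F/F cells stood behind these values, 131 against 363, and the median of all genes in the class was shifted by 0.11 on the log2 scale; under scaling by the median ratio, the cytotoxicity list stood at 0.35. The same list was also higher in plasma-like cells, with a median of 0.25, and in macrophage-like cells, with 0.27. Whether these counts are expression, free RNA or doublets was not tested. The median was 0.12 (-0.02 to 0.24) in cluster 0, led by cytotoxic genes, and -0.03 in CD4 T-like cells. Whether the shift was particular to CD8 T-like cells therefore cannot be said. Without the 5 highest cells of each library, S100a6 moved from 0.534 to 0.898, Hist1h2ap from 2.67 to 1.27, Lgals1 from 0.466 to 0.607, Ube2c from 0.417 to 1.20 and Xcl1 from 0.304 to 0.485. Ratios above 1 moved up for Klrk1 (3.69 to 10.95, with 16 of 20 F/F UMIs in 5 cells), Gpr183 (2.80 to 5.93), Mib1 (3.34 to 6.42) and Aff1 (2.42 to 3.45). A fixed 5 cells is a larger part of 131 F/F than of 363 CD4-Cre cells, so the step by itself tends to raise ratios. These rises therefore do not show that a difference holds without the highest cells.

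Dendritic cells and macrophages, in which CD4-Cre is not meant to act, also differed. In cDC1-like cells the cytokine gene Il12b was at 15.7 and 70.5 CPM, a ratio of 4.50 (3.60 to 5.67), seen in 5.62% and 9.71% of cells. Ccl22, a chemokine of migratory dendritic cells, had a ratio of 3.24 (2.81 to 3.74) and was seen in 8.28% and 16.1%. Cxcl9, a chemokine induced by interferon-γ, was lower, 250 and 112 CPM, a ratio of 0.448 (0.411 to 0.487), but was seen in 31.1% and 29.1% of cells, and Rhob and Rgcc stood at 0.439 (0.364 to 0.529) and 0.451. Immediate early genes had a median of -0.34 in these cells, with 12 of 14 lower. In macrophage-like cells Chil3 was at 74.4 and 320 CPM, a ratio of 4.30 (3.87 to 4.79), seen in 3.47% and 8.04%, and Tmtc2 had a ratio of 2.72 (2.08 to 3.57). Retnla was at 322 and 93.7 CPM, from 25 and 7 cells, and Il1rapl2 at 78.8 and 25.6 CPM, from 19 and 10 cells. The heat shock gene Hspa1b had a ratio of 0.323 (0.234 to 0.439), and glycolysis genes a median of 0.19 (0.10 to 0.27), with 13 of 16 higher. Few cells held most UMIs of several of these genes. Without the 5 highest cells of each library the ratio was 8.96 for Il12b, 6.45 for Ccl22 and 0.528 for Cxcl9. It was 7.27 for Chil3, 0.0348 for Il1rapl2 and 0.00339 for Retnla. For Retnla this left out 5 of 7 positive CD4-Cre cells against 5 of 25 in F/F. The step takes a larger part from the library with fewer positive cells, so it can move a ratio away from 1 by itself. Serpinb1a and Fabp5 in cDC1-like cells moved from 3.32 each to 2.29 (1.31 to 4.23) and 1.71 (0.974 to 3.10), while Dscam and Ly6k in macrophage-like cells moved from 6.54 and 3.15 to 7.10 (2.91 to 20.9) and 2.88 (1.63 to 5.29).

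In plasma-like cells Apoe stood at 1.95 (1.85 to 2.06), but 1546 of its 3711 CD4-Cre UMIs came from 5 cells, and without such cells the ratio was 1.19. Gstp1 stood at 1.5 (1.45 to 1.55), and Ifi27l2a, Hist1h2bb and Hist1h2bj at 0.577 (0.563 to 0.591), 0.547 and 0.565. Ifi27l2a was thus lower in CD4 T-like, CD8 T-like and plasma-like cells alike. The enterocyte RNA (sorted out by EPCAM) list median in plasma-like cells was a log2 ratio of 3.20 (1.97 to 5.13) over 5 measured members, with Lgals4 at 28 and 844 UMIs, but it depended on the setting: 0.45 with every cell weighted equally, 0.31 with free RNA genes left out of the clustering, 0.30 and 0.25 with the mitochondrial share at most 20% and 5%, and 5.89 with free RNA of barcodes with 10 to 100 UMIs subtracted. It was -2.96 (-5.69 to -1.87) over 3 members in cDC1-like cells, and in macrophage-like cells Reg3b, its 1 measured member and a free RNA gene of the F/F library, stood at 41 and 2 UMIs. In cluster 17, Cd4 was at 46.9 and 197 CPM, a ratio of 4.19 (3.24 to 5.50), Nr4a1 had a ratio of 0.497 (0.406 to 0.61), Gzma 0.542 (0.472 to 0.622) and Ccl4 0.414 (0.294 to 0.58), or 0.637 without the 5 highest cells of each library.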

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

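The tests in this part were chosen after the result was seen. Barcodes with 150 to 350 UMIs hold free RNA and are not among the cells compared. They carried transcripts of gastric genes at higher levels in the CD4-Cre than in the F/F library, and the organ of origin was not tested. Tff2, a trefoil peptide of mucous neck cells, stood at 4841 CPM against 399 CPM, and Gkn3 at 1055 CPM against 69.6 CPM. Agr2 stood at 359 CPM against 11.3 CPM, Tff1 at 159 CPM against 0.068 CPM, and Muc6 at 149.7 CPM against 27.2 CPM. The gene 2310057J18Rik stood at 85.5 CPM against 4.50 CPM, Gkn2 at 57.5 CPM against 0, and Gkn1 at 31.8 CPM against 0.068 CPM. In barcodes with 10 to 100 UMIs Tff2 stood at 469 CPM against 80.2 CPM and Gkn3 at 100.3 CPM against 8.83 CPM.

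These 8 gastric genes took 0.674% of the UMIs of the barcodes with 150 to 350 UMIs in the CD4-Cre library and 0.0512% in F/F, while 25 genes picked for higher free RNA in F/F, mostly pancreatic but with Reg3b, also an enterocyte gene, took 1.36% in F/F and 0.00463% in CD4-Cre. Free RNA in the droplets would add about the same number of UMIs to shallow and deep cells: CD4 T-like over plasma-like cells, the mean UMIs of these 25 genes per F/F cell, over the lower 90% of cells, had a ratio of 1.05 (0.999 to 1.09), and gastric UMIs per CD4-Cre cell 0.994 (0.937 to 1.05), although median depth was 3514 against 17450 UMIs in F/F. Free RNA is thus a likely source of these transcripts in T cells, but not of most UMIs in kept cells: cluster 9 holds 85.1% of the UMIs of the 25 genes in F/F, and plasma-like cluster 1, where 2 cells have over 100, holds 72.1% of the gastric UMIs in CD4-Cre. Whether the tissue taken with the intestine differed between the pools, or the genotype had a part, cannot be told apart with 1 library per genotype.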

How the results depend on the processing

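Without the doublet setting, 176 values of 14 main results under alternatives stayed within the counting interval, 29 moved and 1 reversed; for 186 single genes and other lists the numbers were 2585, 315 and 19. All values are log2 ratios or list medians, alternatives marked added were chosen after seeing the data, and, unless stated, the cause was not tested. Gramd1a in CD4 T-like cells stayed between -0.59 and -0.09, within its interval. Cd4 stood at 1.57 in cells of T clusters with a Cd4 UMI and no Cd8a or Cd8b1 UMI, a gate that selects on Cd4 itself, at 2.35 with at most 5% mitochondrial UMIs and at 2.06 at resolution 0.5. Il17a stood at -0.35 with 2000 UMIs, -0.36 without free RNA genes (added), -0.43 and -0.15 with at most 20% and 5% mitochondrial UMIs, -0.37 with readout genes kept and -0.47 with the cycling cluster (added); each class then held the cell with 279 Il17a UMIs. It stood at -0.62 under the Cd4 gate. The share of cells with Il17a stayed between -0.97 and -0.58. The T cell receptor activation list stood at -0.33 under median ratio scaling, -0.354 at resolution 2, and -0.35 and -0.346 with the cycling cluster and without its highest Il17a cell (both added). At resolution 0.5 it reversed to 0.003 and the cholesterol list stood at -0.37; that class holds 424 and 590 cells, as many as cluster 12 within 1 cell per library. The type 17 list stood at 0.053 with at most 5% mitochondrial UMIs and -0.46 at resolution 2. Shares moved with their denominator: of cells other than B-like and plasma-like, CD4 T-like cells stood at 0.33, cDC1-like at 0.28 and macrophage-like at -0.70; of cells also outside pancreatic and mixed clusters (added), CD4 T-like stood at 0.08, CD8 T-like at 0.98, ILC3-like at 0.022, cDC1-like at 0.03 and macrophage-like at -0.94. Plasma-like cells stood at -0.12 without Cd4 (added), -0.13 with 500 UMIs, -0.26 without free RNA genes (added) and -0.119 with at most 20% mitochondrial UMIs. Among single genes, Hist1h2ap in CD8 T-like cells reversed to -0.39 without Cd4 and -0.34 with readout genes kept, and Ube2c there to 0.27 without the 5 highest cells (added). Serpinb1a in cDC1-like cells reversed to -0.10 with 500 UMIs and -0.22 at resolution 2, and Uhrf1 in CD4 T-like cells to -0.25 without cells over 8000 UMIs or 10% immunoglobulin (added). In CD4 T-like cells the immediate early list reversed to 0.079 under the Cd4 gate and 0.003 at resolution 0.5. The immunoglobulin list there reversed to 0.014 with 2000 UMIs, 0.028 without cells over 8000 UMIs or 10% immunoglobulin, 0.021 with at most 5% mitochondrial UMIs and 0.004 with the cycling cluster without its highest Il17a cell. The same list reversed to 0.102 in CD8 T-like cells with the plateau profile subtracted (added), and to -0.031 in plasma-like cells with every cell weighted equally. Equal weight took oxidative phosphorylation in CD8 T-like cells to 0.008. In plasma-like cells, CPM without immunoglobulin and similar genes took glycolysis to 0.024 and sterol transport to 0.014, and median ratio scaling took them to 0.035 and 0.024. Both settings shift all genes of a class by the same amount, so these reversals of medians near 0 follow from the rescaling. Keeping doublets moved nothing because 0 were called, and resolution 0.5 named no CD8 T-like class, so it gave no value there. No paired analysis was possible because each genotype is 1 pool. Depth limits the shares: with a median of 3514 and 3220 UMIs, CD4 T-like cells without a cytokine UMI may still express the gene; thinning to 1500 UMIs lowered the Il17a share from 9.88% to 7.74% and from 6.33% to 4.43% (log2 ratio -0.81).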

Other observations

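The tests in this part were chosen after the result was seen. The 2 CD4 T-like clusters differed in their lists, a difference that was not tested. Cluster 12 was led by Ikzf2, Icos, Maf and Il10 among others, with a Foxp3 UMI in 46.1% of cells. An Il17a UMI was seen in 13.7% of its F/F and 8.15% of its CD4-Cre cells, so its values are not those of regulatory T cells alone. In cluster 12 the median of cholesterol synthesis and SREBP2 targets was -0.38 (-0.59 to -0.19), with 17 of 20 members lower in the CD4-Cre library. In cluster 16, marked by Ccl5 and Gzma, it was 0.24 (-0.11 to 0.33). T cell receptor activation was the other way round, 0.01 in cluster 12 and -0.49 (-0.62 to -0.28) in cluster 16, and all 10 proliferation genes were higher in cluster 16, with a median of 0.39. Proliferation genes had medians of -0.09 (-0.32 to 0.02) in cluster 12, -0.37 in cluster 17, -0.999 in cluster 0 and -1.64 in cluster 13. Few cells carry some of these values: 5 F/F cells held 101 of 121 Stmn1 UMIs in cluster 0, and in cluster 16, 5 cells held 28 of 51 F/F and 75 of 183 CD4-Cre Pclaf UMIs. Il2 was seen in 11 F/F and 5 CD4-Cre cells of cluster 16 and in 0 cells of cluster 12.

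Cd4 was higher in the CD4-Cre library beyond the CD4 T-like class, with ratios of 4.02 (1.86 to 10.3) in CD8 T-like cells, 11.05 (4.09 to 41.9) in the unnamed cluster 0 and 7.43 (2.94 to 24.1) in cluster 13, where 5 cells held 36 of 76, 28 of 57 and 31 of 41 CD4-Cre UMIs. Other classes had smaller ratios or few UMIs, 1.31 (1.18 to 1.45) in plasma-like, 2.10 (1.22 to 3.76) in cDC1-like and 1.47 (1.14 to 1.90) in macrophage-like cells, or 1.27, 2.48 and 1.28 (0.957 to 1.71) without the 5 highest cells of each library, and 1 against 24 UMIs in B-like and 1 against 16 in ILC2-like cells; whether these are expression, free RNA or doublets was not tested. Free Cd4 RNA is argued against, because the log2 ratio in CD4 T-like cells was 2.18 (2.08 to 2.29) after free RNA was subtracted. This interval is the one before subtraction moved to the new value, so it leaves out the error of the free RNA estimate. A larger part of CD4 lineage cells in the class was weighed with Cd40lg, Icos, Cd5 and Cd28, whose highest log2 ratio was 0.19 (Cd5), under a bound of 1. A Cd4 UMI was already seen in 57.4% of F/F cells of the class, so such a shift could hardly have reached that bound. The markers therefore cannot decide, but the same 57.4% leaves little room for this shift alone to give the Cd4 ratio of 4.62. A candidate explanation is Cd4 sequence carried by the CD4-Cre transgene, which stays open beside an effect of the deletion, since 0 libraries carry the transgene without the deletion.

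Il17a was lower in CD4 T-like cells of the CD4-Cre library, and 3 technical explanations were weighed. Lower depth is argued against, because the share of cells with Il17a, thinned to 1500 UMIs, had a log2 ratio of -0.81 (-1.33 to -0.27). For a few F/F cells with many UMIs, the log2 CPM ratio without the 5 highest cells of each library was -1.28 (-1.51 to -1.06). That step also took out CD4-Cre cells and moved the ratio further down from -1.16, so it cannot decide by itself. The share of cells with Il17a counts each cell once and was 9.88% and 6.33%. A few such cells are therefore argued against for the share of cells. Placement of Il17a cells in other clusters is argued against for the share of cells, because over CD4 T-like, cycling and mixed clusters together the share was 8.93% and 5.22%, a log2 ratio of -0.77 (-1.16 to -0.40), but the Il17a log2 ratio in CD4 T-like cells depended on it: -0.47 with the cycling T cluster, and -1.18 with the cycling T cluster and without its highest Il17a cell, which held 279 UMIs. Fewer Il17a-expressing cells with CD4-Cre may be a biological difference, but variation between pools, which 1 pool per genotype cannot measure, stays open.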
